A study of Homo sapiens with 24 samples.

How the data were processed

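Small RNA was measured in HEK293T cells, a human embryonic kidney line that carries the SV40 large T antigen. The cells had been fed 4-thiouridine (s4U), a uridine analogue that growing cells build into new RNA. Per the labels' protocols, the small RNA cultures received 100 µM s4U, total RNA was extracted, and the thiol of s4U was coupled to biotin with a methanethiosulfonate reagent (MTS-biotin). Biotinylated RNA was bound to streptavidin beads and released by cleaving the disulfide with dithiothreitol. The released fraction is called the eluate, and RNA that had not been enriched is called the input. Of the 24 samples of the series, 16 small RNA libraries were used: 14 eluates and 2 inputs. The other 8 samples hold long RNA and were not analysed here. No eluate from cells without s4U was used for small RNA, so the background of the enrichment was not measured in these libraries.

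The deposited count table holds estimated counts per mature miRNA for each library, without scaling for depth. It lists 2548 miRNAs, 529 of them with a suffix that the sources used here do not explain, and 1523 had a count in at least 1 library used. Of the non-zero values, 67.0% were whole numbers within 1e-06, and others were simple fractions, the form taken by reads shared between several matching places. Reads were aligned with Bowtie2 2.2.3, per the submitters' processing notes, which also name the hg19 build. The counting rule, adapter trimming and miRNA annotation are not given in the sources used here. Members of near-identical families (miR-20a and miR-20b, miR-17 and miR-106a, the let-7 members, miR-103a and miR-107, the miR-378 members) can exchange reads under such a rule, and their separate values are uncertain. The prefix of human miRNA names is left out of the text. No genome of the build was used, so no coordinates are given, and miRNA sequences and their uridine content were not used here.

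The authors' deposited table of differential expression gives log2 fold changes, mean log2 levels, p-values and false discovery rates, together with a class score of -1, 0 or 1, for 250 miRNAs. The submitters' processing notes name edgeR 3.2.4. The labels list this table for both inputs and for the eluates of 20 min, 1 h (replicate 1), 6 d and 22 d, and give neither which of these were compared nor the direction of the authors' log2 fold changes.

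Columns of the count table were assigned to samples by time point and replicate number. For the 9 h and the 22 d eluate, the number in the column name differed from the one in the sample title, so each was used as the single library of its time point, without a number. Estimated counts were rounded to whole numbers. Total counts per library ran from 6133 to 1457654, a 238-fold range. The 95% Wilson intervals for shares, the exact Poisson and binomial intervals for ratios of few counts and the limit of 3 counts for a miRNA not seen all cover counting error only, since reads without molecular identifiers are not independent molecules.

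Short feeds (20 min and 1 h, 4 eluates) were compared with long feeds (6 d and 22 d, 3 eluates), because the labels tie those time points to the authors' edgeR table. Each was also compared with the 2 inputs as a single group, and the slope of each miRNA on log2 hours of feed was tested over all 14 eluates. These tests used edgeR 4.0.16 in R 4.3.3 with TMM factors, the filterByExpr filter, the quasi-likelihood F test and Benjamini-Hochberg adjustment, with a threshold of 0.05 on the adjusted p. The design, the lists and the alternatives not named below as added later were fixed before the data were examined. The design had assumed whole counts, and the rounded estimated counts took their place. The 2 inputs, with 1 library each, were compared by the ratio of CPM (counts scaled to library size) without a test, for miRNAs with at least 100 counts over both.

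Minor arms were defined from the inputs alone: of a hairpin with at least 20 counts, the arm with a mean level of at most 0.5 times that of the other arm. There were 341 such arms. Their share of reads was correlated with log2 hours by Pearson's r and Spearman's rho with 100000 permutations, two-sided. Lists of miRNA families and clusters, of miRNAs made by non-canonical routes, of an imprinted cluster, of miRNAs typical of serum or other tissues, and of the minor arms were tested with camera in limma 3.58.1 with a preset correlation of 0.01 and with an estimated one. Minor arms were left out of the families. The imprinted chromosome 14 cluster had no member above the filter.

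Named miRNAs were taken by rule. In the comparison of short with long feeds these were the 10 largest folds in each direction among miRNAs past the threshold with a mean of at least 10 CPM and no overlap between the groups. In the other tests these were 5 in each direction. The 10 most abundant miRNAs of the inputs and examples from each list were added. Levels are CPM (counts scaled to library size) with TMM factors, as mean ± SD. For time points they come from 1 scaling over all 16 libraries, and for a comparison from the libraries compared, so the values of a miRNA differ slightly between paragraphs.

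The tests were run on simulated counts with known changes, up and down in equal number, in part of the miRNAs. All miRNAs had the same fixed dispersion, and no change larger than 8-fold was simulated. The shares recovered count only changed miRNAs that passed the filter. For the short against long feeds, 110 changed miRNAs were among the 256 tested. The share recovered was 43.8% for 2-fold, 94.9% for 4-fold and 100% for 8-fold changes, and 4.26% of the calls were false. For the long feeds against the inputs, 21.4% of 2-fold and 88.5% of 4-fold changes were recovered among 476 tested. For the short feeds against the inputs these shares were 19.5% and 90.7% among 286 tested, and for the trend 40.0% and 91.4% among 266. False calls made up 5.51% of the calls for the long feeds against the inputs and 3.09% for the short feeds against the inputs. For the trend they made up 5.26%.

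Alternatives were other scalings, other filters, DESeq2 1.42.0, limma-voom, a 2-fold minimum, other time points in the groups, only the input of fed cells, a replicate block, and leaving out each library in turn. Added after seeing the data were thinning of libraries to a common depth, fits without the miR-4521 hairpin, without libraries under 20000 counts or limited to numbered libraries, the authors' star arms, and the arms with the family seed in the miR-16, miR-181 and miR-130 families. Replicate libraries of a time point were compared by a chi-square test. In all 6 pairs the statistic exceeded its degrees of freedom, by 2.56 to 94.2 times, and none held identical values, so each was counted as a sample. Such an excess shows spread beyond counting error, not separate cultures. Plots and shares were computed with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.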

Results

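miRNAs were sequenced from HEK293T cells fed s4U for 20 min, 1 h, 3 h, 9 h, 1 d, 3 d, 6 d or 22 d, after enrichment of the RNA that had taken up the label. The labelled RNA of a short feed was made within that time, and that of a long feed can be of all ages. An eluate may also hold unlabelled RNA, whose part was not measured here. There were 2 eluates at each of 6 time points and 1 each at 9 h and 22 d. Unenriched small RNA of cells fed for 22 d and of cells without s4U gave 1 input library each. No label says that libraries of a time point came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Depth was uneven: 102303 and 51860 counts at 20 min, 6133 and 139362 at 1 h, 240493 and 15169 at 3 h, and 38269 at 9 h. The 1 d eluates held 475337 and 1070708 counts, the 3 d eluates 72766 and 8788, the 6 d eluates 137169 and 1312900, and the 22 d eluate 1457654. The inputs held 984555 counts with s4U and 1156051 without.

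The steady-state pool of the inputs was led by miR-92a-3p, a member of the miR-17~92 cluster, with 9.66% of miRNA reads. It was followed by miR-148a-3p with 7.28%, miR-10a-5p with 7.24%, miR-7-5p with 6.41%, miR-20a-5p with 5.23% and let-7a-5p with 4.71%. miR-221-3p, miR-30d-5p, miR-10b-5p and miR-26a-5p completed the 10 most abundant, which together took 51.3% of the reads. In 12 of the 14 eluates miR-92a-3p was again the most abundant miRNA. The exceptions were both 20 min eluates, in which miR-4521 came first.

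The time course asked how miRNAs of different age differ in abundance. miR-4521 took 37.7% ± 5.18 of miRNA reads after 20 min (SD, n = 2), 15.4% ± 1.16 after 1 h (n = 2), 5.28% ± 0.0504 after 3 h (n = 2) and 2.85% in the 9 h eluate (95% Wilson interval 2.69 to 3.03). It held 0.150% ± 0.122 after 1 d, 0.168% ± 0.0515 after 3 d and 0.0417% ± 0.00535 after 6 d (n = 2 each), and 0.00864% after 22 d (95% Wilson interval 0.00726 to 0.0103). The share was 0.0927% in the input of fed cells and 0.128% in the input without s4U. Over the 14 eluates it fell with time, with Spearman's rho -0.976 and Pearson's r of log share with log hours -0.976 (permutation p = 1e-05 for both, the smallest that the permutations can give). Without the 2 libraries farthest from the median time r was -0.967. The deposited table also lists a 3p arm of the same hairpin. It followed miR-4521 over the 14 eluates with rho 0.868 (permutation p = 0.00013) and r of log levels 0.919 (permutation p = 4e-05). Without the 2 libraries whose log level of miR-4521 lay farthest from its median, r between the arms was 0.888. Against miR-4521 it held 0.828% of the reads in the short feeds and 0.877% in the inputs. The ratio varied between other time points. It was higher in the long feeds, with 19 counts of the 3p arm and 775 of miR-4521. In the 3 h eluate replicate 1 it was lower, with 47 and 12607.

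**Figure D1:**
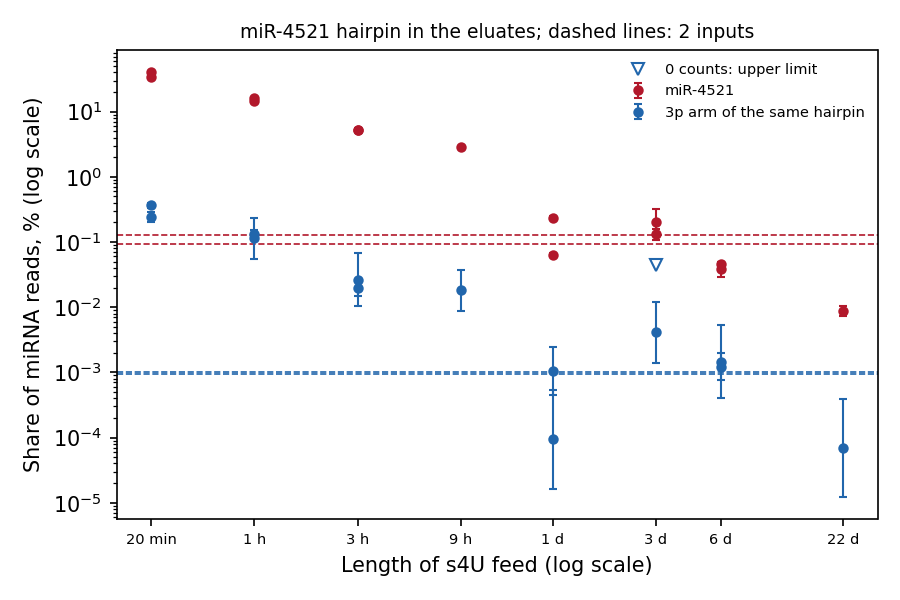
Share of miRNA reads (percent, log scale) taken by miR-4521 and by the 3p arm of its hairpin against the length of the s4U feed (log scale). Points are libraries, bars are 95% Wilson intervals, the open triangle is the upper limit of a library with 0 counts, and dashed lines are the 2 inputs. miR-4521 went from 37.7% at 20 min to 0.00864% at 22 d.

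Over all eluates, the slope on log2 hours passed the threshold for 153 of 288 miRNAs, with 85 rising and 68 falling as the feed lengthened (edgeR quasi-likelihood, adjusted p under 0.05). The steepest rises were those of miR-20b-5p with 0.65 log2 units per doubling of time (SE 0.11, adjusted p = 0.000143), miR-1278 with 0.61, miR-3607-3p with 0.55, miR-215-5p, a p53-responsive miRNA, with 0.50 and miR-106a-5p with 0.49. The steepest falls were those of miR-6892-5p, which was not seen from 9 h on, with a fitted -1.31, miR-4521 with -1.16 (SE 0.06, adjusted p = 1.01e-11), its 3p arm with -1.02, miR-27a-5p with -0.87 and miR-16-1-3p with -0.51. Not all of these were gradual. miR-20a-5p, an oncogenic miRNA of the miR-17~92 cluster, stood at 5064 ± 872 CPM after 20 min (SD, n = 2), 5182 ± 1038 after 1 h, 7258 ± 1828 after 3 h and 7030 in the 9 h eluate. After 1 d it stood at 60618 ± 13892 (n = 2), and the inputs held 51854 and 57559. miR-7-5p, which is known for its regulation by the circular RNA CDR1as, rose in smaller steps. It stood at 9453 ± 2047 after 20 min, 30612 at 9 h and 102082 at 22 d, with 58490 and 76308 in the inputs. miR-16-1-3p held 32.1 ± 4.82 CPM after 20 min, 501 ± 95.9 after 1 h and 4.99 at 22 d. The 3 d libraries of miR-3607-3p, whose hairpin overlaps a small nucleolar RNA, lay far apart (3335 ± 4474, n = 2). With upper-quartile factors in place of TMM, 58 slopes rose and 93 fell.

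**Figure D2:**
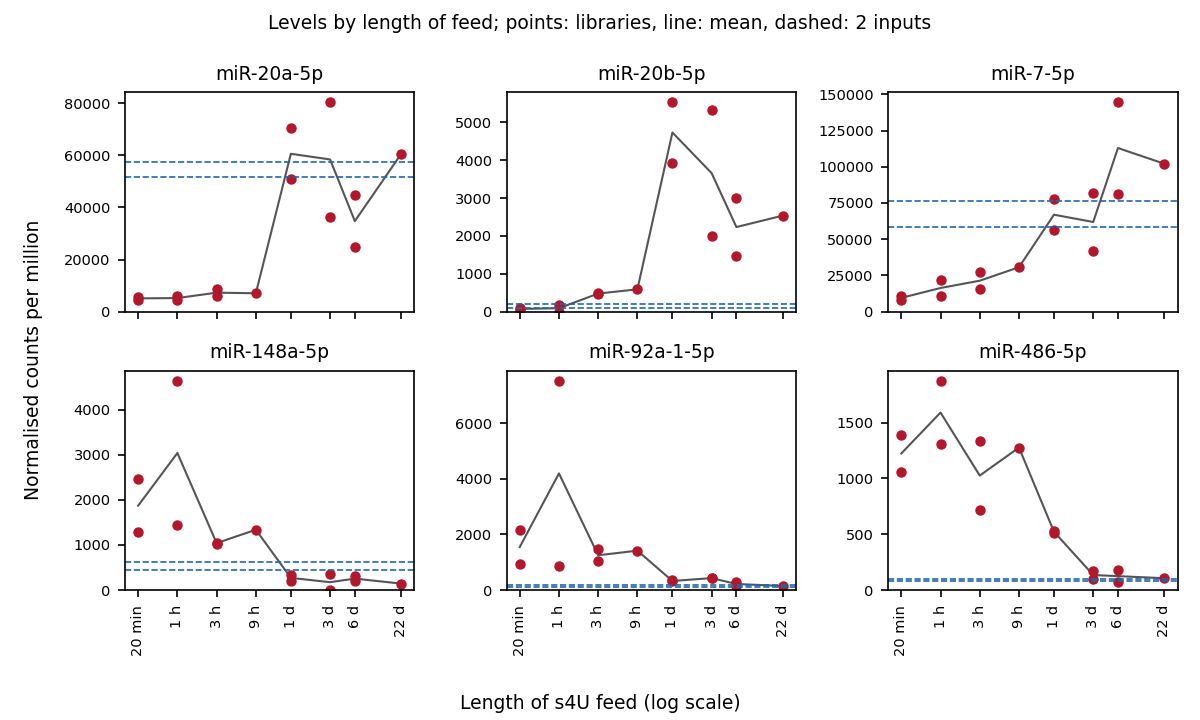
Normalised CPM of 6 miRNAs against the length of the s4U feed (log scale). Points are libraries, lines join the means of time points, and dashed lines are the 2 inputs. miR-20a-5p stood at 7030 in the 9 h eluate and at 60618 on average after 1 d, and miR-486-5p at 1276 in the 9 h eluate and at 522 on average after 1 d.

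The short feeds were compared with the long feeds to separate miRNAs that are prominent soon after their synthesis from those that are prominent in the aged pool. Past the threshold were 152 of 263 miRNAs, 69 higher in the short feeds and 83 higher in the long feeds (edgeR quasi-likelihood, adjusted p under 0.05, n = 4 and 3). The 4 short-feed and 3 long-feed libraries did not overlap for 136 miRNAs (51.7%, where chance gives 5.71%). miR-4521 was 1022-fold higher in the short feeds (log2 fold change 10.00, SE 0.79, adjusted p = 3.13e-12), and its 3p arm was 335-fold higher (8.39, SE 0.72). miR-6892-5p had 54 counts in the short feeds and 0 in the long feeds, which makes it at least 175-fold higher against a limit of 3 counts over the group. miR-27a-5p, the less abundant strand of the miR-27a hairpin, stood at 557 ± 399 CPM in the short feeds (SD, n = 4) and 2.38 ± 2.49 in the long feeds (n = 3), a log2 fold change of 7.06 (SE 0.71, adjusted p = 5.04e-10).

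Further miRNAs higher in the short feeds were miR-766-3p with a log2 fold change of 3.64, miR-92a-1-5p with 3.64, miR-615-5p, from a hairpin in the HOXC cluster, with 3.31, miR-148a-5p with 3.25, miR-486-5p with 3.18 and miR-1226-5p with 3.17. Their adjusted p in edgeR lay between 6.9e-07 for miR-148a-5p and 3.01e-05 for miR-1226-5p. The short-feed levels of miR-766-3p, miR-615-5p and miR-1226-5p rested on 37, 58 and 29 counts. That of miR-92a-1-5p varied widely between libraries (2255 ± 2467 CPM, SD, n = 4), so the sizes of these folds are uncertain. Of the miRNAs higher in the long feeds, miR-7-5p and miR-20a-5p were the most abundant. miR-7-5p stood at 10241 ± 4792 CPM in the short feeds and 106330 ± 27402 in the long feeds, a log2 fold change of -3.37 (SE 0.41, edgeR adjusted p = 2.64e-08). miR-20a-5p stood at 4106 ± 834 and 42990 ± 19331, a log2 fold change of -3.41 (SE 0.38, edgeR adjusted p = 5.32e-09). miR-20b-5p had the log2 fold change -4.75, miR-3607-3p -3.70, miR-106a-5p -3.68 and miR-378c -3.28. Few counts lay behind the short-feed level of the others. miR-215-5p had 4 counts in the short feeds and 616 in the long feeds (8.28 ± 9.90 against 203 ± 49.1 CPM, log2 fold change -3.88, edgeR adjusted p = 2.02e-05). miR-378i had 1 count in the short feeds and 397 in the long feeds (ratio of CPM 0.0244, 95% counting interval 0.000617 to 0.137). miR-1278 had 3 against 465 (ratio 0.0626, 0.0129 to 0.184), and miR-561-5p 3 against 365 (ratio 0.0798, 0.0164 to 0.235). For miR-20b-5p, which is nearly identical in sequence to miR-20a-5p, the counts per 100 counts of miR-20a-5p were 0.185 in the input without s4U, 0.399 in the input of fed cells and 1.26 to 8.36 in the eluates by time point.

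Upper-quartile factors moved the median log2 fold change of all miRNAs from -0.30 to 0.26 and gave 89 higher and 57 lower calls. Library-size factors moved this median to -0.41. Thinned to the 6133 counts of the shallowest library, the libraries gave 38 calls among the 67 miRNAs still tested.

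**Figure D3:**
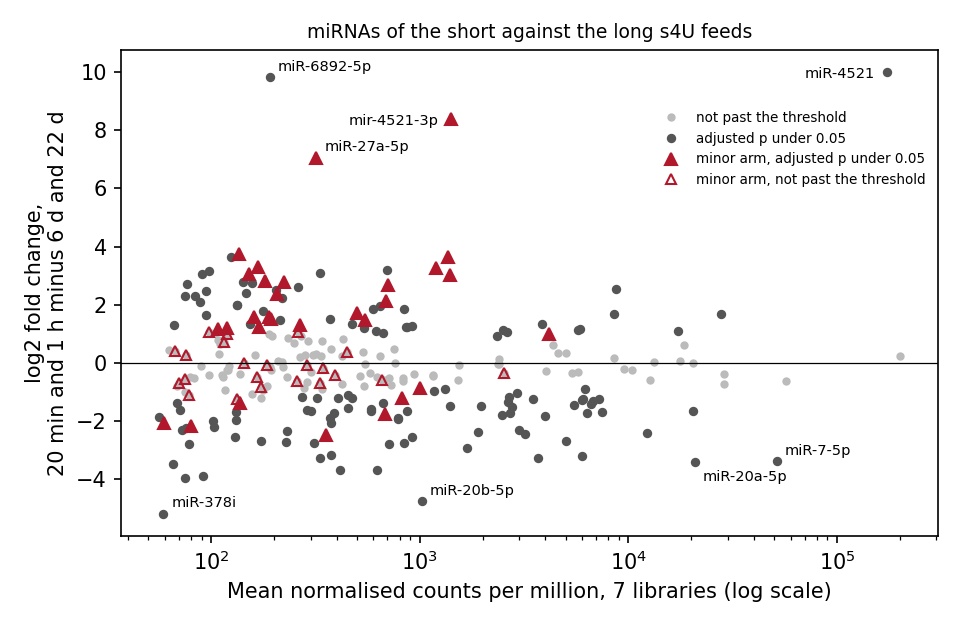
Log2 fold change of the short (20 min and 1 h) over the long (6 d and 22 d) feeds against the mean level (CPM, log scale) for 263 miRNAs. Dark points passed the threshold, and triangles are minor arms, filled where they passed it. Of the 52 minor arms, 23 were higher and 7 lower in the short feeds.

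Among the families and clusters fixed before the data were examined, the miR-17~92 cluster, a polycistron driven by MYC, had 0 members higher in the short feeds, 5 lower and 1 not past the threshold. The count adjusted over the list alone was also 5. miR-20a-5p was lower with a log2 fold change of -3.41, miR-19a-3p with -2.93, miR-19b-3p with -2.39, miR-18a-5p with -1.21 and miR-17-5p with -0.90. miR-92a-3p, whose counts are not tied to a single hairpin, had 0.25 (SE 0.41, edgeR adjusted p = 0.617). As a set the cluster missed the threshold (camera adjusted p = 0.0985, and adjusted p = 0.537 with an estimated correlation), and with upper-quartile factors 3 members were lower. The paralogous miR-106b~25 cluster had 2 of 4 members lower, miR-106b-5p with -1.66 and miR-93-5p with -1.42, and miR-25-3p had 0.01. The 2 measured members of their X-linked paralogue, miR-106a-5p and miR-20b-5p, were lower, but their sequences are nearly identical to miR-17-5p and miR-20a-5p, so their separate values are uncertain.

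Within the let-7 family, which acts against proliferation, 3 of 9 members were lower in the short feeds, let-7g-5p with -1.73, let-7f-5p with -1.31 and let-7i-5p with -0.98. miR-98-5p was 2.83-fold higher and 5 members did not pass. Upper-quartile factors gave 1 higher and 2 lower, and library-size factors 0 higher and 4 lower. Of the 7 measured arms with the seed of the extended miR-16 family, 5 were lower and 0 higher, among them miR-15a-5p with -2.75, miR-16-5p with -1.81 and miR-107 with -1.67. miR-503-5p, known for rapid decay, had -0.73 (SE 0.43, edgeR adjusted p = 0.143). Upper-quartile factors left 3 lower and library-size factors 4. The fixed list also held 2 opposite arms without the seed, miR-424-3p, which was higher with 1.85, and miR-15b-3p. The group of miR-10, miR-99, miR-100 and miR-125 was split. miR-99b-5p with 2.54, miR-125a-5p with 1.13 and miR-125b-5p with 1.06 were higher, and miR-10b-5p with -1.67 and miR-100-5p with -1.68 were lower, while upper-quartile factors left 1 of the lower calls.

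In the miR-181 family, miR-181a-5p with -2.29, miR-181b-5p with -1.19 and miR-181c-5p with -1.37 were lower, and upper-quartile factors left 1 of the 3. miR-181d-5p had 0.25 (SE 0.40), and miR-181c-3p, an opposite arm without the family seed that the fixed list held, was higher with 2.29. Of 5 miR-30 members, miR-30e-5p with -1.73 and miR-30a-5p with -1.29 were lower, and with upper-quartile factors 1 was higher and 1 lower. Of the miR-221 and miR-222 pair, miR-222-3p was higher with 1.69 and miR-221-3p had -0.21 (SE 0.35, edgeR adjusted p = 0.626). Of the arms with the seed of the miR-130 and miR-301 family, miR-454-3p with -1.98 and miR-301a-3p with -2.07, from 8 counts in the short feeds, were lower. miR-130b-3p had -1.25 (SE 0.59, edgeR adjusted p = 0.0722), and the count adjusted over the list alone was 3 lower. The fixed list had kept miR-301a-5p with 2.60 and miR-130b-5p with 0.92 in place of the 3p arms, since these were the minor arms in the inputs, and so gave 2 higher and 1 lower, or 1 and 1 with library-size factors. In the clusters of miR-23, miR-27 and miR-24, 1 of 5 was higher and 2 were lower, miR-27b-3p with -1.25 and miR-27a-3p with -1.12, but upper-quartile factors gave 2 higher and 0 lower, and library-size factors 0 higher and 2 lower. In the cluster of miR-183, miR-96 and miR-182, miR-96-5p was lower with -1.65, and upper-quartile factors added 1 higher. The single measured members of the miR-29 and miR-200 families, miR-29a-3p with -0.37 and miR-200c-3p with -0.79, did not pass. With upper-quartile factors the medians of the let-7, miR-10, miR-30, miR-23, miR-183 and miR-29 lists turned from below to above 0. For every fixed list in these families and clusters, the counts adjusted over the list alone equalled those over all miRNAs. None of those with at least 3 measured members passed as a set in camera, where adjusted p ranged from 0.0985 to 0.838.

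Of the miRNAs made by non-canonical routes, miR-1226-5p, from a mirtron spliced out as a short intron, and miR-484, from a hairpin at a transcription start, were higher in the short feeds (log2 fold changes 3.17 and 1.32). miR-320a had 0.03 (SE 0.33), and 3 of 5 did not pass (camera adjusted p = 0.602 for the list). Of the miRNAs typical of blood, muscle and other tissues, 3 of 4 were higher in the short feeds: miR-486-5p with 3.18, miR-486-3p with 3.05 and miR-133a-3p with 2.46. miR-1-3p had -0.87 (SE 0.49). The arms miR-486-5p and miR-486-3p come from a single hairpin. miR-133a-3p had 0 counts in the 1 h eluate replicate 1 and stood at 784 CPM, without TMM factors, in the 9 h eluate. Whether the cells made these miRNAs or the reads are background was not tested. The list did not pass as a set (camera adjusted p = 0.165, and adjusted p = 0.537 with an estimated correlation). miR-486-5p, an erythroid and muscle miRNA, stood at 1223 ± 228 CPM after 20 min and 1590 ± 404 after 1 h (SD, n = 2 each), 106 at 22 d, and 84.3 and 97.7 in the inputs.

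miRNA hairpins give a major arm, which is kept by Argonaute, and a minor arm, which is mostly discarded, and the arms were compared to see how they differ with age. Minor arms took 3.27% ± 1.01 of miRNA reads in the short feeds (SD, n = 4) and 3.18% ± 0.785 in the 3 h, 9 h and 1 d eluates (n = 5). They took 2.03% ± 0.371 in the long feeds (n = 3) and 1.66% ± 0.067 in the inputs (n = 2). The share fell with the length of feed over the 14 eluates with rho -0.628 (permutation p = 0.018) and r -0.572 (permutation p = 0.032). Without the 2 libraries farthest from the median time, both 20 min eluates, r was -0.836. As a share of all miRNA reads, the fall did not start at 20 min. The eluates there held 2.73% and 2.41%, near the 2.39% and 2.46% of the 1 d eluates. With both arms of miR-4521 left out, the 20 min eluates held 4.07% and 3.30%, above the 2.39% and 2.46% of the 1 d eluates. The highest shares were 4.70% in the 1 h eluate replicate 2 and 4.29% in the 9 h eluate. Without the 6 d eluate replicate 2 rho was -0.548 (permutation p = 0.054) and without the 22 d eluate -0.535 (permutation p = 0.061). Without the miR-4521 hairpin the share was 4.12% ± 0.941 in the short feeds and rho was -0.819 (permutation p = 0.00061). Adjusted over the 3 relations computed across the eluates (Benjamini-Hochberg), the permutation p of rho was 3e-05 for miR-4521, 0.000195 for its arms and 0.018 for the minor arms, and that of r was 3e-05, 6e-05 and 0.032. Counting any lower arm as minor gave rho -0.389 (permutation p = 0.16), and the median share within hairpins, which was 0 in 8 of the eluates, gave rho 0.0943 (permutation p = 0.74).

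Of 52 minor arms tested between short and long feeds, 23 were higher and 7 lower in the short feeds, against 46 higher and 76 lower of the 211 other miRNAs (Fisher's exact test, two-sided, p = 0.00153 for higher and 0.00143 for lower). Besides miR-27a-5p, examples were let-7a-3p with a log2 fold change of 3.01, miR-191-3p with 3.06, miR-25-5p with 2.67 and let-7f-2-3p with 3.75. miR-140-5p with -2.50 and miR-17-3p with -1.76 were lower. In 37 of the 52 hairpins the minor arm had the higher fold change, with a median difference of 1.09 log2 units (exact sign test, two-sided, p = 0.00319). This contrast was clear in let-7a, where let-7a-5p had -0.73, and in miR-25, where miR-25-3p had 0.01. As a set the minor arms passed in camera (adjusted p = 0.00712), and the call was lost with an estimated correlation (adjusted p = 0.537 with an estimated correlation). Fisher's test and the sign test count miRNAs of the same libraries, which are not independent replicates. Choosing minor arms by a low level in the inputs can also favour higher fold changes in the short feeds.

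**Figure D4:**
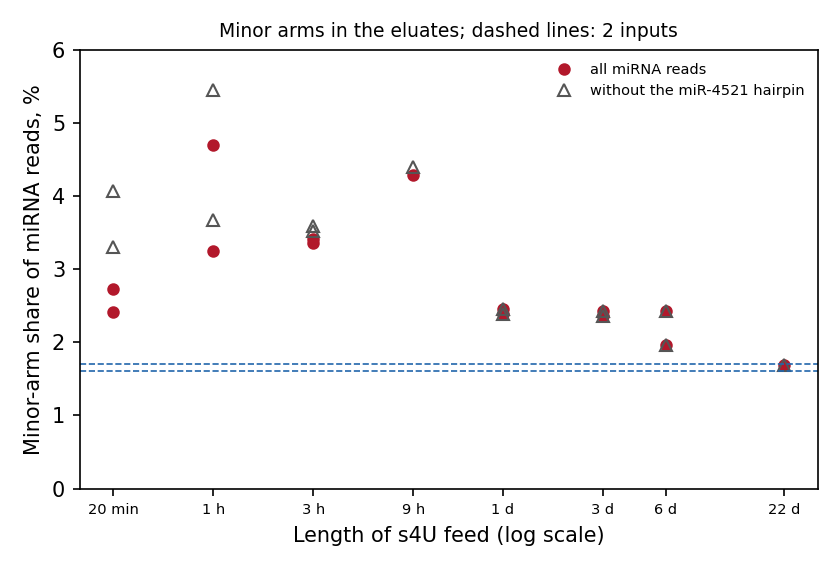
Share of miRNA reads from minor arms (percent) against the length of the s4U feed (log scale). Circles are eluates, triangles are the same eluates without the miR-4521 hairpin, and dashed lines are the 2 inputs. The short feeds averaged 3.27%, the 3 h, 9 h and 1 d eluates 3.18%, the long feeds 2.03% and the inputs 1.66%.

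Long feeds were compared with the inputs to see which miRNAs the enrichment leaves over- or under-represented after long labelling. Of 487 miRNAs, 63 passed the threshold, 35 higher and 28 lower in the eluates (edgeR quasi-likelihood, n = 3 and 2). miR-20b-5p stood at 2327 ± 706 CPM in the long feeds and 150 ± 72.9 in the inputs, a log2 fold change of 3.95 (SE 0.53, edgeR adjusted p = 0.00437). miR-146a-5p, an immune miRNA induced by NF-kappaB, had 3.53, but its inputs lay apart (29.4 CPM with s4U and 3.91 without) and the log2 fold change against the input of fed cells alone was 2.64, so its size depended on the input. miR-378i had 3.52 and the haematopoietic miR-142-3p 3.34, from 56 counts in the long feeds and 5 in the inputs. Without the 6 d eluate replicate 2, miR-146a-5p and miR-142-3p no longer passed, and without the input of fed cells miR-212-3p no longer passed. miR-5698 rested on 61 counts in the long feeds, 51 of them in the 6 d eluate replicate 2, and 2 in the input of fed cells against 0 in the other (ratio 22.5, 95% counting interval 5.96 to 190). Lower in the long feeds were miR-671-5p, which guides cleavage of CDR1as, with -3.52, miR-210-3p, the hypoxia miRNA, with -2.73, miR-212-3p with -2.67, miR-425-3p with -2.55 and miR-1307-5p with -2.51. miR-671-5p stood at 62.6 ± 33.9 CPM in the long feeds and 731 ± 152 in the inputs (edgeR adjusted p = 0.00437). Against the input of fed cells alone 1 miRNA passed, miR-671-5p, and against the input without s4U alone 24 passed, in fits where the lone input was assumed to vary like the eluates. Against the input of fed cells, miR-378i had 3.68 and miR-425-3p -2.61, near the values with both inputs, and miR-20b-5p had 3.44. Without the 6 d eluate replicate 1 there were 104, DESeq2 gave 127, and library-size factors gave 109.

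Short feeds were compared with the same inputs to set the newest miRNAs against the steady-state pool. Of 268 miRNAs, 172 passed the threshold, 77 higher and 95 lower in the short feeds (edgeR quasi-likelihood, n = 4 and 2). miR-4521 was 280.5-fold higher than in the inputs (log2 fold change 8.13, SE 0.76, adjusted p = 1.68e-06), its 3p arm had 8.04 and miR-27a-5p 5.75. miR-6892-5p had 54 counts against 2 (ratio of CPM 193, 95% counting interval 50.9 to 1633), and miR-4443 had 23 against 2 (ratio 82.2, 20.3 to 719). Lower in the short feeds were miR-20a-5p with -3.65 (SE 0.25, edgeR adjusted p = 1.36e-07), miR-32-5p with -3.81, miR-374b-5p with -3.49, miR-1278 with 3 counts against 311 (ratio 0.0689, 0.0141 to 0.203) and miR-651-5p with 1 against 206 (ratio 0.0347, 0.000874 to 0.195). miR-374b-5p was thus 11.2-fold lower in the short feeds. With upper-quartile factors 105 were higher and 64 lower, and the median of all miRNAs moved by 0.61 log2 units, against 0.22 with DESeq2-type factors.

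Whether 22 d of s4U altered the miRNA profile was addressed by the 2 inputs, which have no replicates. Across 264 miRNAs with at least 100 counts, Spearman's rho was 0.981, a value across miRNAs, which are not independent replicates. Of these, 95.5% lay within 2-fold, 10 were over 2-fold higher with s4U and 2 were over 2-fold lower, but with TMM factors 4 were higher and 3 lower. miR-203a-3p was 2.71-fold higher with s4U (108 against 39.8 CPM), followed by miR-6516-3p with 2.53-fold, miR-152-3p with 2.42-fold, miR-20b-5p with 2.27-fold and miR-328-3p with 2.18-fold. miR-34a-5p, a transcriptional target of p53, was 3.34-fold lower with s4U (25.4 against 84.8 CPM, from 25 and 98 counts), followed by miR-486-3p with 2.05-fold, let-7d-5p with 1.94-fold, miR-98-5p with 1.79-fold and let-7i-5p with 1.78-fold. With a minimum of 20 counts, 35 of 445 miRNAs lay beyond 2-fold, and with a minimum of 1000 counts 2 of 120.

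The authors' deposited table of 250 miRNAs shared 232 with the short against long comparison. Across those miRNAs, which are not independent replicates, its log2 fold changes correlated with the fitted ones at r -0.996, so its sign is coded the other way, with miR-4521 at -10.79 and miR-20b-5p at 4.35 in the authors' deposited table. The 2 sets were also offset: the sum of the 2 values had a median of -0.61, and 41 of the 232 had the same sign in both. Of the miRNAs that the authors' deposited table lists with a false discovery rate under 0.05, 122 were tested in both and 98 of them passed here. The 41 shared miRNAs that the authors' deposited table puts in class 1 or -1, a separate count, all passed here with the opposite sign.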

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

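Thinning, leaving out the miR-4521 hairpin or the libraries under 20000 counts, the fits limited to numbered libraries, the authors' star arms and the arms with the family seed were chosen after seeing the data; the other alternatives were fixed before. Short against long feeds gave 152 calls, 124 to 156 when each library was left out, and 250 without a filter, 234 with a mean of at least 10 CPM, 38 with all 7 libraries thinned to the shallowest and 88 with the 6 deeper ones thinned to 51860 counts. The trend gave 153 calls, 115 to 156 with each library left out, and 339 without a filter. More or fewer miRNAs were tested under these filters and depths (1283, 461, 67, 178 and 1450). Long feeds against inputs gave 63 calls, 1 to 104 with each library left out (1 with only the input of fed cells and 24 with only the other, fits with 1 library in an arm), 99 with DESeq2-type factors, 109 with library size only and 127 with DESeq2; the cause of the other changes was not tested. Short feeds against inputs gave 172 calls, 139 to 180 with each library left out, and stayed within 1.5 times in the other settings run. The inputs differed beyond 2-fold for 12 miRNAs, for 35 and 2 with minimums of 20 and 1000 counts, and for 7 with TMM factors. The minor-arm rho of -0.628 was -0.389 with any lower arm, -0.243 with the arms the authors marked as star, 0.0943 for the median within hairpins, and -0.797 to -0.535 with each library left out. Of the lists 1 passed, also 1 with only the arms with the family seed, and 0 with an estimated correlation. miRNAs named for the size of their fold or slope kept direction and call in all 413 refits that tested them of short against long feeds, 135 of short feeds against inputs and 239 of the trend, and in 115 of long feeds against inputs, where 13 others fell below the threshold; members of lists were followed only across scalings, where some calls were lost. Replicate numbers did not pair the libraries at all time points: the correlations of deviations between time points ran from -0.574 to 0.524, and 7 of 15 were over 0.1. Among the 20 min, 1 h, 1 d and 3 d eluates they ran from 0.16 to 0.524, and with the 3 h or 6 d eluates from -0.574 to 0.121. Of 12 libraries, 6 correlated best with their own number. With the replicate block there were 134 calls between short and long feeds (141 for the same libraries without it) and 144 for the trend (134 without it). The alternatives for normalized values were not run because the table holds counts. Depth limits the 1 h eluate replicate 1 and the 3 d eluate replicate 2, where 3 counts stand for 489 and 341 CPM.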

Other observations

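The tests of miR-4521 and of miR-20b-5p and the fit without the miR-4521 hairpin were chosen only after the result was seen, and the curvature fit was added after the time courses had been looked at. Some miRNAs did not follow a straight line in time. When a squared term of log2 hours was added, 39 of 343 miRNAs curved downward and 21 upward (edgeR quasi-likelihood, adjusted p under 0.05). The examples were picked after their values were seen. Of the downward curves, miR-31-5p stood at 202 ± 41.5 CPM after 20 min (SD, n = 2), 2938 in the 9 h eluate (145 counts), 2332 ± 214 after 1 d (n = 2) and 516 at 22 d (edgeR adjusted p = 0.00104). miR-193b-3p stood at 421 ± 16.4 after 1 h and 694 ± 108 after 3 h (n = 2 each), 972 in the 9 h eluate (48 counts) and 24.2 at 22 d (edgeR adjusted p = 0.00521). Upward curves included let-7a-3p with 3487 ± 1847 after 20 min (n = 2), 81.0 from 4 counts in the 9 h eluate and 434 at 22 d (edgeR adjusted p = 0.00262). The abundant miR-10a-5p stood at 77124 ± 7702 after 20 min, 29789 ± 2126 after 3 h, 30088 ± 2796 after 1 d (n = 2 each) and 80188 at 22 d (edgeR adjusted p = 0.0134). The input with s4U held 68608 CPM of it and the input without s4U 83226, so the 20 min eluates lay at input level. Whether unlabelled RNA contributed to this curve was not tested. None of the other 99 orders of the feed times tried gave as many downward curves (1 of 100 with the real order, highest other 33). These orders removed the straight trend together with any curve, so they do not test curvature apart from the trend. Without the single 9 h eluate 18 passed, 17 of them among the 39. This is below the bound of 0.5 times the 39 that was set before the fit without that library, so the 9 h eluate stays open as a source of the other downward curves.

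If each library is an independent sample, a chance assignment can be excluded at the 0.05 level as a source of the calls. This holds for the short against the long feeds and for the trend. The comparisons with the inputs were not tested in this way. Of the 35 splits of the 7 libraries, 1, the real split, gave 152 calls, and the highest other gave 92. That split set the 1 h eluate replicate 1, the shallowest library, with the long feeds. Of 100 orders of the feed times, 1, the real order, gave 153 calls in the trend, and the highest other gave 56. If libraries of a time point are technical, the time points are the units. Those of the short and long feeds are then too few to reach the 0.05 level, and the orders of the trend moved single libraries.

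miR-4521 led the 20 min eluates and was scarce in the inputs. Carry-over of unlabelled RNA in the proportions of the inputs would give their share, but the 20 min share was 341 times as high. No small RNA eluate from cells without s4U was used, so unlabelled RNA held by the beads in other proportions was not tested. Depth is argued against by the 6 eluates of 30000 to 150000 counts, where the lowest short-feed share was 5.67 times the highest of the others. Reads of an unrelated RNA matching a single arm would leave the 3p arm behind, whereas the arms moved together (rho 0.868). The share fell with the feed (rho -0.976), as fast synthesis and fast loss would give. Turnover alone would also bring the long feeds to the level of the inputs, but the share was 0.0417% ± 0.00535 at 6 d (SD, n = 2) and 0.00864% at 22 d, below the 0.0927% in the input of fed cells. The long feeds against both inputs missed the threshold (log2 fold change -1.84, SE 0.58, edgeR adjusted p = 0.0584), so turnover stays open. Unlabelled RNA held in other proportions stays open too, as does an s4U-rich RNA that matches both arms of the hairpin, which was not tested.

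More minor arms were higher (23) than lower (7) in the short feeds, and 22 did not pass. Their median log2 fold change of 0.85 lay outside the central 95% of 10000 sets of other miRNAs matched on level (-0.78 to 0.29). Minor arms were chosen for a low level in the inputs, and only those past the filter in the short and long feeds were tested. That choice can favour arms that are high in the short feeds, and matching on level does not remove it. Low abundance thus stays open. Leaving out the miR-4521 hairpin kept the fall of the minor-arm share (rho -0.819). The lowest share in a short-feed eluate was 2.41%, above both inputs (1.61% and 1.71%), which argues against carry-over in the proportions of the inputs alone. No biological explanation was tested. Uridine content of the arms was not tested either, and the call as a set was lost with an estimated correlation.

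miR-20b-5p rose with the feed and exceeded the inputs, but its counts may partly be reads of miR-20a-5p in which s4U was read as C. Per 100 counts of miR-20a-5p there were 0.185 (95% exact interval 0.152 to 0.223) in the input without s4U and 2.16 times as many in the input of fed cells (1.70 to 2.74). The lowest value of any eluate time point was 1.26 (0.461 to 2.77), from 6 counts of miR-20b-5p at 20 min, as this explanation needs. The value was 8.36 at 9 h and 4.18 at 22 d, so it did not rise throughout. More true miR-20b-5p in the eluates would also give values above the input without s4U, so they do not single out misread miR-20a-5p. Slower turnover of miR-20b-5p alone would leave the 22 d eluate near the input of the same feed, but the ratio there was 10.5 times as high (9.13 to 12.1). The reads were not used here, so T-to-C changes in them were not examined.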
